A study of Homo sapiens with 2 samples.

How the data were processed

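RNA sequencing measured gene expression in CaSki cells, an established human cervical carcinoma line, in 2 libraries. Per the labels, 1 library came from cells transfected with an siRNA against DLEU2 and 1 from cells transfected with a control siRNA, both with a lipid reagent. The treatment label of the control library names the control siRNA, while its description calls the cells wild type; the treatment label was used. Total RNA was the starting material, per the labels' protocols. Strandedness and the way in which ribosomal RNA was depleted are not given in the sources used here.

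HISAT2 2.0, edgeR and the hg38 build are named in the submitters' processing notes, without their roles. Each gene has an FPKM and an estimated count per library, per the file headers, in 1 table made by the authors. The table holds 58825 entries under 48868 gene symbols. FPKM is given per gene, and most entries with a count of 0 carry an FPKM of 0.0001 in the deposited table. The deposited estimated counts did not behave as a plain tally of fragments, given the excess of counts of 4 described below. In genes with a single transcript and over 500 counts, the count equalled FPKM times transcript length times a constant of the library within 1% for 82.4% of 744 genes in the control library and 81.4% of 703 genes in the DLEU2 siRNA library. That constant was 76.1 counts per FPKM and kilobase in the control library and 71.2 in the DLEU2 siRNA library. Tallied reads could meet this relation too, so it does not decide how the counts were made. Counts of 4 were more frequent than their neighbours, with 943 entries at 4 against 363 at 3 and 188 at 5 in the DLEU2 siRNA library. Counts were therefore divided by 4 before any counting interval was computed, so that 1 unit stands for about 1 sequenced fragment. This reading rests on the values, and no header or label states it.

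No test across conditions was possible with 1 library per group, and no p-value was computed. The log2 ratio was log2 of the DLEU2 siRNA FPKM plus 1 over the control siRNA FPKM plus 1, which understates the change of genes with low FPKM. It was taken for genes with a mean FPKM of at least 1, with the entry of higher mean FPKM where a symbol had several. Genes at least 2-fold apart on this scale were counted. Fold ratios were ratios of estimated counts divided by the library constants, with exact 95% intervals conditional on the sum of both counts; these cover counting error only. No intervals between replicates exist here.

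Before the data were examined, 30 gene lists were fixed. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 3 measured members was said to stand apart outside the middle 95% of them, as a description of these 2 libraries. The genes named in the text were set beforehand as DLEU2, the 12 genes with the highest and the 12 with the lowest log2 ratio apart from placeholder locus names, and up to 4 members per list at least 2-fold apart or else the member farthest from 0. The rule also took the measured members of the DLEU2 locus list, NOTCH1, CDKN1A, CCND1 and BCL2. Genes named outside it are marked where they appear. Some genes that the rule takes, and 1 of the lists, are counted in the totals but not reported here.

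Transcript length, GC content and 3' UTR sequence came from the GENCODE 29 annotation, used by gene identifier. It held 99.5% of the table's identifiers, and 81.3% of these had the same start and end, so the release behind the table is not known and coordinates are those of the table. For each gene the protein-coding transcript with the longest 3' UTR was used, which gave a length to 9603 of the 10962 measured genes. For a scan of 7-base words in 3' UTRs of at least 50 bases, log2 ratios limited to 2 in size were regressed on the ranks, and squared ranks, of transcript length, 3' UTR length, both GC contents and mean FPKM. The mean residual of the genes holding a word was divided by its standard error to give z, for words in at least 50 genes. Genes were said to have a large overlap when an overlapping entry, on either strand, held over 25% of their counts.

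The size rule and the list step were tested on data simulated from the control library, with counting error as the only noise. Measured log2 ratios had a standard deviation of 0.497, so these tests do not give the rate of wrong calls between real libraries. The size rule found 47 of 50 genes made 3-fold higher and 36 of 50 made 3-fold lower. Of 50 genes made 1.5-fold higher and 50 made 1.5-fold lower, it found 0 and 1. Planted genes that fell under the minimum FPKM counted as not found. Among the 10783 simulated genes past that minimum, it took 8 of 10590 unchanged genes. Of 100 lists of 25 genes shifted by a log2 ratio of 0.3, 100 stood above the random lists, against 8 of 100 lists with no shift outside the range. For the word scan, measured log2 ratios were instead shuffled among genes within 10 bins of transcript length. A word then planted with a shift of 0.12 in 718 genes came first among all words.

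Alternatives fixed beforehand were pseudocounts of 0.1 and 5, each library rescaled to the same sum, centring on the median gene, summed entries per symbol, a minimum mean FPKM of 5, no filter, and a 1.5-fold size rule. Rescaling took FPKM sums of 301421 with control siRNA and 280701 with DLEU2 siRNA to a larger common sum. It therefore also lowered the weight of the added constant and of the minimum FPKM. Alternatives chosen after seeing the data were estimated counts scaled by their total, protein-coding genes with no large overlap, log2 ratios levelled over transcript length, random lists matched on length and expression, and the DLEU2 locus list without DLEU2 after rescaling. Computations used Python with numpy, pandas and SciPy.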

Results

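Gene expression in CaSki cells, an established human cervical carcinoma line, was compared between 1 library from cells given an siRNA against DLEU2 and 1 library from cells given a control siRNA. DLEU2 is a long noncoding RNA gene on chromosome 13 and hosts the microRNA genes MIR15A and MIR16-1. The estimated counts summed to 63122379 in the control library and 59409888 in the DLEU2 siRNA library, or 15780595 and 14852472 after division by 4. Counts above 0 were given for 20449 and 20658 entries. There were no replicates, so every difference below is between these 2 libraries and has no replicate check. Intervals of ratios and counts cover counting error only, and intervals of mean adjusted log2 ratios come from resampling genes.

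DLEU2, the target of the siRNA, was lower in the library labelled DLEU2 siRNA. The gene (ENSG00000231607, hg38 chromosome 13, 49956733 to 50125541, minus strand) had an FPKM of 0.827 with control siRNA and 0.183 with DLEU2 siRNA. Its estimated counts were 342 and 72, which is 77.5% lower for the depth of each library, with a 95% counting interval of 62.3% to 87.3%. With 1 FPKM added to both values the log2 ratio was -0.63, because DLEU2 lay under the minimum of 1 FPKM used for other genes. Several annotated genes overlap DLEU2, DLEU1 on the opposite strand among them, and reads from them cannot be told apart without strand. DLEU1 had counts of 271 and 211, and TRIM13, within DLEU2 on the opposite strand, 717 and 750. The overlapping RNA entries RF02104 and RF02103 had 464 and 294, and 275 and 251. By the rule stated for overlaps, DLEU2 thus had a large overlap. The ratio of its whole locus was not computed, so the 77.5% rests on how reads were assigned among these entries. MIR15A and MIR16-1, which lie within DLEU2, were listed with a count of 0 in both libraries. DLEU1, RF02104, RF02103, MIR15A and MIR16-1 lie outside the naming rule. Among its neighbours, SPRYD7 had a ratio of 0.665 (0.534 to 0.826) and EBPL a ratio of 0.769 (0.661 to 0.894). KPNA3 had a ratio of 1.26 (1.12 to 1.42) and RCBTB1 of 0.888 (0.678 to 1.16), while TRIM13, inside DLEU2, had 1.12 (0.906 to 1.38). The median log2 ratio of the 5 measured genes at this locus was -0.10, at the 20.7th percentile of random lists, and none was 2-fold apart. After each library was rescaled to the same sum, which let more of its genes past the minimum, DLEU2 itself among them, the median of this list was -0.27 at the 1.32th percentile. Without DLEU2, a setting chosen after seeing the data, it was -0.17 over 10 genes at the 4.46th percentile, within the range.

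The genes that differed most between the libraries included the immediate early genes IER2 and JUND, both far lower with DLEU2 siRNA, and the heat shock family member HSPA2 and the junction protein gene F11R, both far higher. IER2 had an FPKM of 29.2 with control siRNA and 1.03 with DLEU2 siRNA, a ratio of 0.0355 (0.0267 to 0.0462). JUND, an AP-1 subunit gene, had 39.6 and 4.61, a ratio of 0.117 (0.0981 to 0.138). F11R had 5.85 and 57.4, a ratio of 9.79 (8.97 to 10.7), and HSPA2 had 0.436 and 12.7. ZNF146 and MED29 were higher by 10.3 and 8.79 times. SRP9, a signal recognition particle subunit gene, had a ratio of 0.203 (0.188 to 0.218), ATP5F1D of the mitochondrial ATP synthase 0.196 (0.171 to 0.224), and C1GALT1C1, which encodes a chaperone of O-glycan synthesis, 0.145 (0.115 to 0.182). Among 10962 measured genes, 273 were at least 2-fold higher and 194 at least 2-fold lower with DLEU2 siRNA, and the median log2 ratio was 0.03. Of these, 53 had placeholder names.

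**Figure D1:**
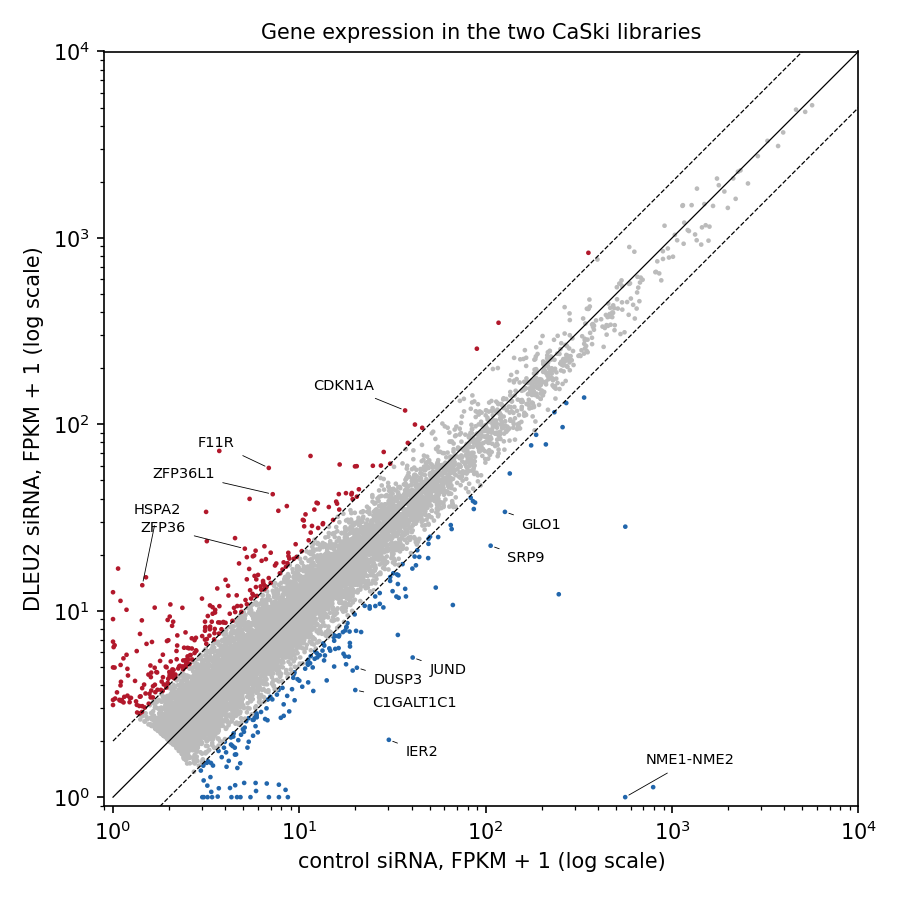
Each point is 1 of 10962 genes, with FPKM plus 1 in the control siRNA library on the horizontal axis and in the DLEU2 siRNA library on the vertical axis, both on log scales. Red points are the 273 genes at least 2-fold higher and blue points the 194 at least 2-fold lower, dashed lines mark 2-fold, and IER2 and JUND lie well below them.

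Of the 24 genes at both ends of the ranking, 9 shared their place with a large overlapping entry, and for 7 of these the difference was under 2-fold once the counts of all overlapping entries were summed. They were the readthrough entries ATP6V1G2-DDX39B, RPL17-C18orf32, NME1-NME2 and TGIF2-RAB5IF and the small RNA entries SNORD22, SNORA57 and MIR1244-1. NME1-NME2 had 52785 counts with control siRNA and 0 with DLEU2 siRNA, while the log2 ratio of its whole locus was -0.53. ATP6V1G2-DDX39B had counts of 491 and 11989, and its locus a log2 ratio of -0.18. For DUXAP8 and ZSWIM9 the locus kept log2 ratios of 2.95 and 2.60. The pseudogene entries TRMT112P6, FTH1P5, IKBKGP1, MTND1P23 and RPL17P50 and the gene CXorf49B have near-identical copies elsewhere, so their values are uncertain. TRMT112P6 and IKBKGP1 were listed with a count of 0 in the control library and with 307 and 445 in the DLEU2 siRNA library.

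The lists of mesenchymal and matrix genes and of TGF-beta, YAP and TAZ targets had higher medians than random lists, with few members 2-fold apart. ITGAV, an integrin subunit gene, had a ratio of 5.17 (4.21 to 6.40), the collagen gene COL5A1 2.86 (2.54 to 3.23), the tenascin gene TNC 2.31 (2.21 to 2.41) and TGFBI 2.11 (2.04 to 2.18). Of 25 measured mesenchymal and matrix genes, 22 lay above 0, 4 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.49. The median was 0.51 for 18 TGF-beta targets, with TGFBI the 1 gene at least 2-fold higher, and 0.41 for 24 targets of YAP and TAZ, the Hippo pathway effectors, where AMOTL2 was farthest from 0 at 0.94. All 3 medians were above those of all 10000 random lists. Fibroblast markers had 4 measured members with a median of 0.42, at the 94.7th percentile, and COL1A1 had an FPKM of 1.23 and 2.44. Endothelial markers reached at most an FPKM of 0.983 and had 0 measured members, and white blood cell markers had 1, CD68, at 9.51 and 11.4.

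Immediate early and AP-1 genes moved in both directions. Besides IER2 and JUND, FOSL2 was lower, with a ratio of 0.411 (0.378 to 0.446), while ZFP36, which encodes an mRNA decay factor, was higher at 5.01 (4.21 to 5.99). Of 23 measured members, 16 lay above 0, 3 were at least 2-fold higher and 3 at least 2-fold lower. The median of 0.34 stood at the 99.99th percentile. Squamous differentiation genes, with SPRR1B at a ratio of 3.41 (1.80 to 6.87) and the desmoglein gene DSG3 at 2.63 (2.28 to 3.04), had a median of 0.26 over 17 genes, 9 of them above 0, at the 99.4th percentile. That median was 0.098 and no longer apart, at the 49.4th percentile, when each library was rescaled to the same sum. This rescaling also lowers the weight of the minimum FPKM and the added constant. Pseudocounts of 0.1 and 5 changed the call of none of the 28 lists, which argues against the added constant alone. With no filter on FPKM the squamous list also lost its call. Centring on the median gene shifts all log2 ratios alike, so it cannot move a list among random lists and tests none of these calls. Replication-dependent histone genes had a median of 0.24 over 20 genes at the 98.3th percentile, with HIST1H2BJ farthest from 0 at 0.77, and mitochondrially encoded genes had 0.03 over 15 genes at the 99.1th percentile, with MT-ATP8 at 0.44. After the same rescaling the histone list was at the 87.1th percentile, and in counts scaled by their total the mitochondrial list was at the 82.2th. Centring could not change the place of either list.

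Genes of the ribosome and of oxidative phosphorylation were lower with DLEU2 siRNA. Among 77 cytoplasmic ribosomal protein genes, 71 lay below 0, and the median log2 ratio of -0.32 stood at the 0.02th percentile. RPL14 was the 1 member at least 2-fold lower, with a ratio of 0.409 (0.394 to 0.424). Among 70 nuclear genes of oxidative phosphorylation, 67 lay below 0, and the median of -0.35 was below all random lists. ATP5F1D and ATP5MG, both of the ATP synthase, were the 2 at least 2-fold lower, and ATP5MG had a ratio of 0.437 (0.409 to 0.467). Both medians stayed below 0 under each scaling tried.

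Cell cycle genes leaned lower without standing apart among lists matched on expression. Of 44 G1/S and DNA replication genes, 34 lay below 0, with a median of -0.16 at the 3.64th percentile. The cyclin D1 gene CCND1 was the 1 member at least 2-fold higher, at a ratio of 2.12 (2.05 to 2.21). CDKN1A, the gene of the cell cycle inhibitor p21, had an FPKM of 35.9 with control siRNA and 118 with DLEU2 siRNA, a ratio of 3.28 (3.12 to 3.44). Of 39 mitotic genes, 27 lay below 0, with a median of -0.12 at the 12.6th percentile and HMMR farthest from 0, with a ratio of 0.391 (0.316 to 0.482). Against lists matched on transcript length as well, chosen after seeing the data, these medians stood at the 0.03th and 0.66th percentiles.

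Published targets of miR-15/16 had a median of 0.26 over 28 genes, at the 99.6th percentile. WEE1, a mitotic inhibitor kinase gene, had a ratio of 3.74 (3.21 to 4.38), CCND1 was the other member at least 2-fold higher, and BCL2 was near the floor with an FPKM of 0.114 and 0.107. Epithelial adhesion genes had a median of 0.23 at the 99.3th percentile, with GRHL2 lower at -0.98, and genes of the WNT pathway 0.25 at the 98.6th. With lists matched on length as well, these 3 were no longer apart, at the 94.3th, 96.0th and 85.5th percentiles. The median of the epithelial list was -0.037 when genes under a mean FPKM of 5 were left out.

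The Notch receptor gene NOTCH1 and its ligand gene JAG1 were higher, with ratios of 2.88 (2.52 to 3.30) and 2.19 (2.03 to 2.37), but the 31 measured Notch pathway genes had a median of 0.03 at the 41.3th percentile. Among NF-kB and cytokine genes, PTGS2 and TNFAIP3 had ratios of 2.95 (2.42 to 3.61) and 2.16 (1.98 to 2.35), and the list a median of 0.10 at the 76.0th percentile. The interferon list had a median of -0.06 at the 14.7th percentile, with IRF9 farthest from 0 at a log2 ratio of 0.82. In counts IRF9 had a ratio of 2.98 (2.11 to 4.30), at an FPKM of 0.602 and 1.83. Other lists within the range were apoptosis regulators at 0.04, with BBC3 at 0.84, and the unfolded protein response at 0.03, with DDIT4 at -0.77. Heat shock genes, also within it, had -0.03, with CHORDC1 at -0.89. In counts BBC3 had a ratio of 2.90 (2.03 to 4.22) and CHORDC1 of 0.469 (0.425 to 0.517), since the added constant draws log2 ratios of low genes toward 0. Hypoxia and glycolysis genes had -0.01, with PFKFB3 at -0.75, cholesterol and fatty acid synthesis -0.01, and NRF2 targets 0.01, where the thioredoxin reductase gene TXNRD1 was 2.85 times higher. The MYC and ribosome biogenesis list had 0.02, with ODC1 at -0.81, and structured RNAs -0.08, where RMRP had counts of 40 and 8. Of 28 lists with a percentile, 11 stood above and 2 below, against 1.4 outside the range by construction of the rule. With no filter on FPKM the squamous, epithelial, WNT, histone and mitochondrial lists no longer stood apart, at the 43.6th, 88.2th, 91.3th, 54.4th and 97.2th percentiles. With log2 ratios levelled over transcript length, chosen after seeing the data, the NF-kB list stood at the 99.6th percentile, apoptosis regulators at the 99.4th and the interferon list at the 0.725th, but against lists matched on length and expression all 3 stayed within the range, at the 89.3th, 73.4th and 20.6th.

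**Figure D2:**
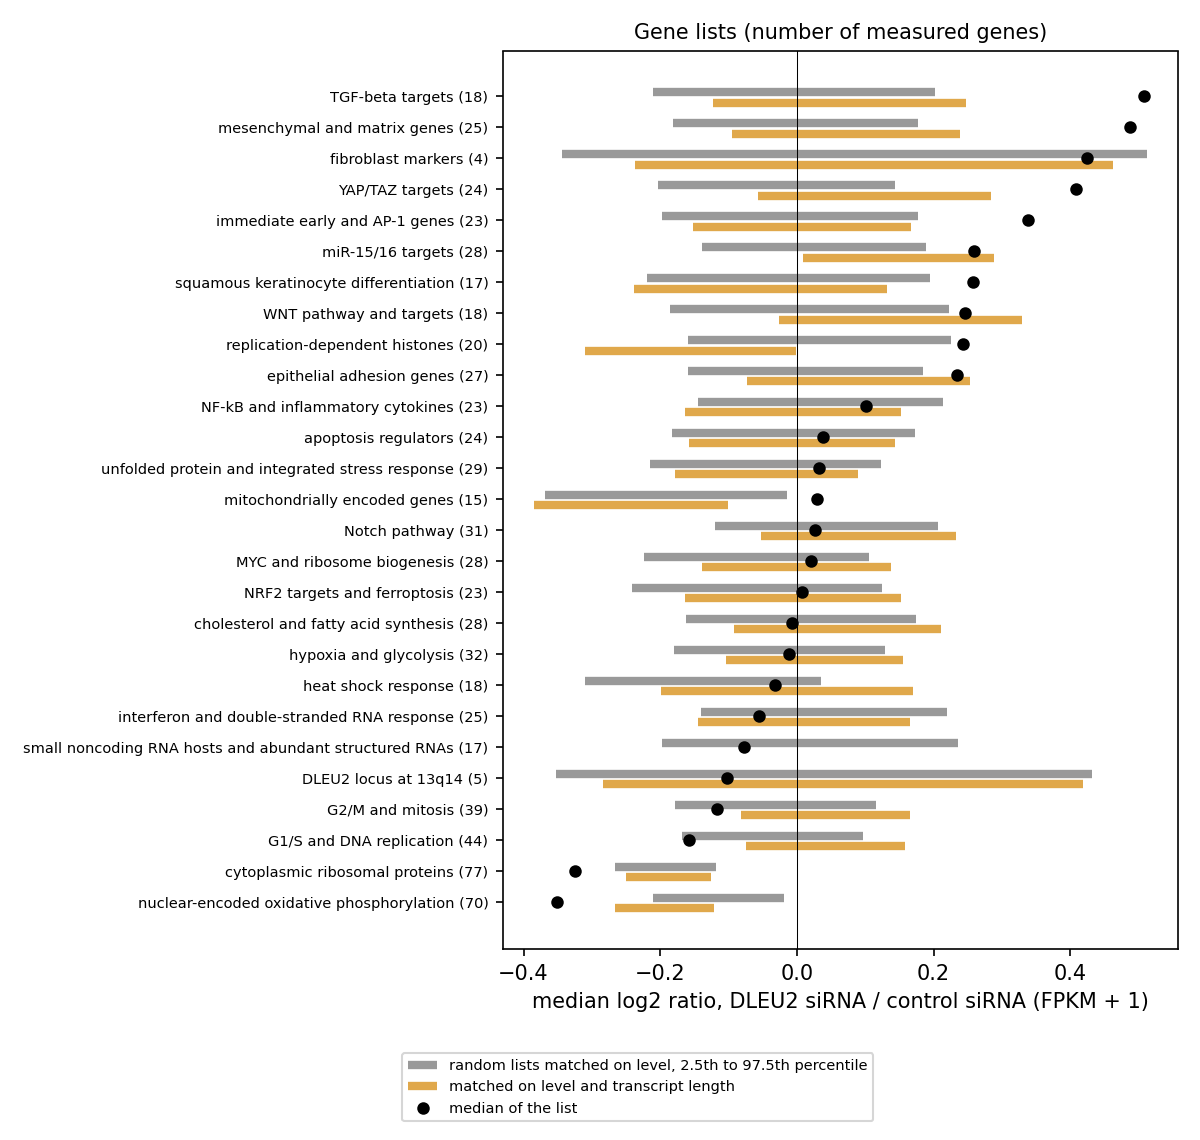
Black points are the median log2 ratio of DLEU2 siRNA over control siRNA for each gene list reported here, with the number of measured genes in brackets. Grey bars span the middle 95% of random lists matched on expression and ochre bars that of lists matched on transcript length as well; TGF-beta targets lie highest at 0.51 and oxidative phosphorylation genes lowest at -0.35.

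Ratios also followed transcript length. Over 9603 genes with a protein-coding transcript, Spearman's rho across genes, which are not independent replicates, was 0.454. The median log2 ratio was -0.25 in the eighth of genes with the shortest transcripts and 0.27 in the eighth with the longest. Ribosomal and oxidative phosphorylation genes have short transcripts, and their medians still stood at the 0 and 0.01th percentiles of lists matched on length and expression. The matched random lists had medians of -0.19 and -0.20, so part of the lower ratios was shared by other genes of like length and expression. The medians of the matrix, TGF-beta, YAP and TAZ and immediate early lists stayed above the range of lists matched in this way.

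**Figure D3:**
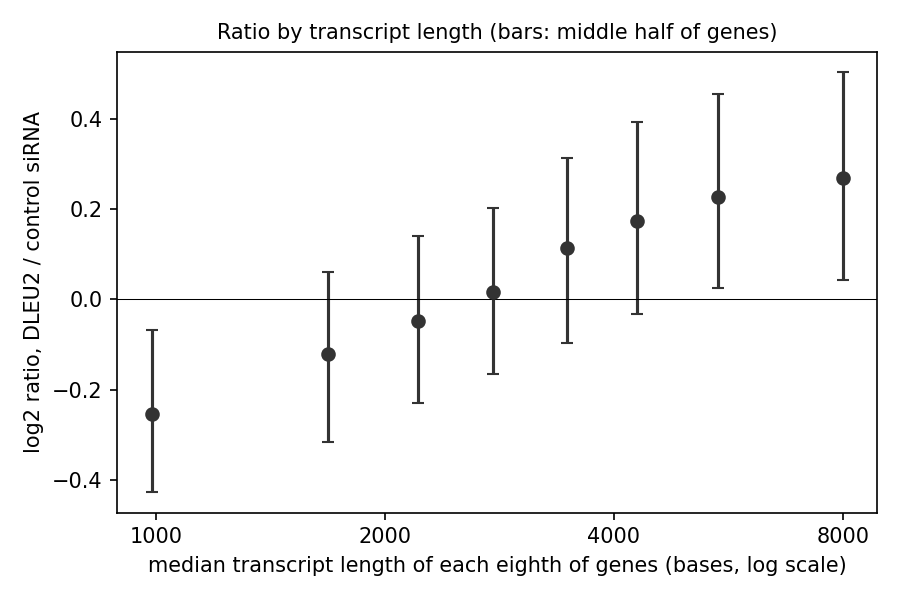
Points are the median log2 ratio of DLEU2 siRNA over control siRNA in each eighth of 9603 genes by transcript length, placed at the median length in bases on a log scale, and bars span the middle 50% of genes. The median goes from -0.25 at a median length of 988 bases to 0.27 at 7997 bases.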

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

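No paired analysis was possible because each group had 1 library and no result came from a test. The fold of DLEU2 in counts needs no pseudocount, but its log2 ratio of -0.63 was -1.71 with a pseudocount of 0.1, -0.17 with 5, -1.18 with each library rescaled to the same sum and -1.54 in counts scaled by their total, which follows from adding a constant to a low value. Counts of genes at least 2-fold higher and lower were 495 and 335 with a pseudocount of 0.1, 72 and 57 with 5, 765 and 375 after that rescaling, and 130 and 113 at a mean FPKM of at least 5. That rescaling raised all values, and so also changed the weight of the added constant and of the minimum. It moved the median log2 ratio of the genes past the minimum by 0.105. Centring on the median gene, which shifts the log2 ratios alone, gave 253 and 210. A 1.5-fold rule gave 970 and 718. In counts scaled by their total 618 genes were higher. Lower genes numbered 95 among protein-coding genes with no large overlap and 115 after levelling over length, in each case with fewer genes tested. Lists standing above were 6 with no filter, which ended the squamous, epithelial, WNT, histone and mitochondrial calls, and lists below were 4 in counts scaled by their total, 5 after levelling over length and 4 with lists matched on length and expression; the cause was not tested. The median of squamous differentiation genes passed to the other side of random lists at 0.098 after rescaling to the same sum and at 0.00041 with no filter, and that of epithelial adhesion genes at -0.037 with a mean FPKM of at least 5. Summing entries per symbol left every list on its side. Centring on the median gene could not move any list among random lists. Of the genes taken by the naming rule other than DLEU2, 18 fell under 2-fold with a pseudocount of 5, and 49 kept their call. After levelling over length, 9 fell under 2-fold, 4 passed it and 43 kept their call. Counts scaled by their total, the overlap filter, levelling, length-matched lists and the DLEU2 locus list without DLEU2 were chosen after seeing the data. DLEU2 rests on few fragments, 18 in the DLEU2 siRNA library (10.7 to 28.4).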

Other observations

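The tests of this part were chosen after the data were examined, except the length tests without ribosomal genes and within 5 bins of expression and of GC content. Pathways annotated in the deposited table were compared with random lists matched on transcript length and expression. Genes of the interaction between matrix and receptors were highest, with a median log2 ratio of 0.58 over 35 genes against 0.19 for the random lists. Of these, 30 lay above 0. Among genes chosen after their values were seen, the laminin genes LAMA3 and LAMB3 had log2 ratios of 0.98 each and the integrin genes ITGA2 1.40 and ITGA6 -0.06. Focal adhesion genes had a median of 0.25 over 118 genes, with 8 at least 2-fold higher and 0 at least 2-fold lower. Genes of the Fanconi anemia pathway, which repairs DNA crosslinks, had a median of -0.14 over 42 genes, and DNA replication genes -0.15 over 34. Of 260 pathways, 26 stood above and 18 below the range, with 6.5 on each side for random lists; pathways share genes.

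Among 7847 protein-coding genes with no large overlap and no placeholder name, 184 were at least 2-fold higher and 95 at least 2-fold lower. Genes named here were chosen after their values were seen. The vitamin D receptor gene VDR had an FPKM of 0.396 with control siRNA and 6.51 with DLEU2 siRNA, the mRNA decay factor gene ZFP36L1 6.20 and 41.2, and the proprotein convertase gene FURIN 1.10 and 7.73. The phosphatase gene DUSP3 had 19.4 and 3.95, CDK2AP1 18.3 and 3.78, and the glyoxalase gene GLO1 126 and 32.9.

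Genes with the word AAGGAAC in the 3' UTR had lower mean ratios than other genes after adjustment for length, composition and expression. Unadjusted medians did not set them below genes with neither the word nor its last 6 bases. The unadjusted median log2 ratio was 0.034 both with 1 site and with neither, 0.072 with 2 or more sites, and 0.099 with the 6-base site only. Genes at least 2-fold lower made up 2.3%, 1.3%, 1.2% and 0.98% of these groups. Over 1122 genes the mean adjusted log2 ratio was -0.12, with z of -10.5, the lowest of all words scanned in 9500 genes. The word was also lowest in each of 2 separate sets of these genes. It had been picked from all of them, and 1 fit to all genes served both sets, so this is not an independent repeat. The lowest word sharing under 5 bases with it had -5.08. That value is itself beyond the -3.58 of a scan of shuffled values, so some structure may remain after the adjustment. Base composition as the whole cause is argued against by a lowest z of -1.66 among 104 rearrangements in the 8378 genes without the word. The fit used all genes, so leaving out the word's low genes raised the mean residual of the rest. These z values are therefore shifted upward, by an amount not removed here. A first form of that test, over all genes, gave -6.24 for a word overlapping it and decided nothing. A candidate explanation is pairing of the transfected siRNA with such sites, since the word stands in all 8 annotated DLEU2 transcripts, as do 0.96% of scanned words, while 23.8% stand in at least 1 of them, which would also have counted as a match. Genes with 1 site lay lower, at -0.12 (-0.14 to -0.09), than genes with a 6-base site, at -0.02 (-0.04 to 0.00), but 2 or more sites, at -0.16 (-0.22 to -0.10), overlapped 1 site, and sites followed by A and other sites both had -0.12, without the gain expected of pairing, so this remains a hypothesis and the siRNA sequence is not given in the sources used here.

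Longer transcripts had higher ratios, with Spearman's rho of 0.454 across genes. Without ribosomal and oxidative phosphorylation genes rho was 0.447, over 9456 of the 9603 genes. They were too few to carry the trend, so this test could hardly have come out otherwise. Expression or GC content does not carry the trend as the whole cause, since the lowest rho within a bin was 0.376 and 0.302. Loss of short inserts is argued against as the whole cause by rho of 0.192 among transcripts over 3000 bases. A difference in RNA integrity or library preparation and an effect of the knockdown were not tested and stay open, since each group had 1 library.

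Published targets of miR-15/16 had higher ratios, as would follow if less DLEU2 gave less of the microRNAs it hosts. Transcript length may account for the group's place, since its median stood at the 94.3th percentile among lists matched on length and expression. The 25 listed targets with a 7-base site had a mean adjusted log2 ratio of 0.147 (0.024 to 0.291), but all 2342 genes with that site had 0.004 (-0.013 to 0.021), and relief of these sites cannot be told apart from other causes. Mature microRNAs were not analysed here.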
